A study of Mus musculus and Macaca fascicularis and Canis lupus familiaris with 796 samples.

How the data were processed

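The data are bulk RNA-seq libraries of tissues, and in a few groups of isolated cells, from mouse, dog, cynomolgus monkey and rat, made with the TruSeq stranded mRNA kit from total RNA per the labels' protocols. The deposited table holds estimated counts per Ensembl gene and library as whole numbers, made with bcl2fastq and Salmon 1.10.1 per the submitters' processing notes. The options, the genome builds, the annotation releases and the way transcripts were summed to genes are not given in the sources used here. Of 2183 libraries in the table, 796 matched a label and were used, and 1387 matched none and were left out. Nearly all of the largest counts end in 0, as rounded values would, but 21 of 655 in monkey and 2 of 354 in dog do not. Genes numbered 56051 in mouse, 30941 in dog, 38352 in monkey and 30257 in rat, and all libraries of a species list the same identifiers. Symbols were available for mouse alone, for 51476 genes (91.84%), which held a median of 98.89% of the counts of a library.

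Libraries were grouped by the species, map and tissue of their labels. The labels give no replicate numbers, so libraries were numbered within each group in the order of their records. Neither sex nor animal is given, and libraries were grouped by labels and never by measured values, so neither was a term of a model, and in the strain comparisons strain goes with map. The rat sets entered the descriptions of depth and of library quality only. Tissues of the 4 largest maps outside the comparisons of groups also entered the counts of tissue-enriched genes, where they had at least 3 libraries.

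Each comparison used the libraries of the groups it names. Genes were filtered with edgeR's filterByExpr (minimum count 10, minimum total count 15), scaled with TMM and tested with edgeR's robust quasi-likelihood F-test. P-values were adjusted with the Benjamini-Hochberg method over all genes tested, and genes with an adjusted p under 0.05 are described as called. Striatum against cortex and hypothalamus against hippocampus in mouse had strain as a covariate. Standard errors are the absolute log2 fold change over the square root of F. Levels are given as TMM-scaled CPM, scaled within a comparison or, for tissue-enriched genes, over a map, so a gene's level differs between them. The interaction of strain and tissue was tested on all 8 interaction terms together over 160 libraries. The chance number of shared genes is the product of the call shares of the single tissues, which holds for independent lists.

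Gene lists fixed before the data were examined were tested in mouse with limma's camera on log CPM, with a preset correlation of 0.01 between genes and, as the alternative, with an estimated correlation. Lists needed at least 5 measured members, and p-values were adjusted over the lists of a comparison. Of 385 list tests 69 were called with the preset correlation and 3 with the estimated one. Members are counted over all genes tested and adjusted over the list alone.

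Genes named in the text follow a rule written before the data were examined. For comparisons of tissues these are the largest changes among called genes with real symbols, a mean of at least 10 CPM in the higher group and no overlap between the libraries of the groups. For strains they are shared genes with at least 5 CPM and the largest changes of each tissue, and for lists the called members with the smallest adjusted p. Xist, Cd8a, Cfd, Plin1 and Ucp1 were singled out in single libraries after their values were seen. In dog and monkey, whose identifiers are paired with no names, at most 2 identifiers rose and 2 fell per comparison. The planned comparison of the chamber effect across species was not run, since it needed symbols in all 3 species.

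A library was said to stand apart when its median correlation of log2 CPM to its group lay more than 0.03 below the median of these values in the group, in groups of at least 3. The correlations are across genes, which are not independent replicates. To find copies, each mouse gene's transcript sequences in a GENCODE annotation were divided into words of 31 bases, and the percentage of words found in another gene was counted.

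The tests were checked on simulated data drawn from the means and totals of real libraries, with 200 genes changed. The percentages of genes recovered at 1.5-fold, 2-fold and 4-fold were 50.7, 82.8 and 98.4 in the cortex strain comparison, over 18832 genes. They were 11.9, 54 and 78.8 in liver (15578 genes), 18.2, 50.8 and 80.3 in dog right atrium against ventricle (16205 genes), 16.4, 45.5 and 80 in dog pancreas (14589 genes), and 73.1, 92.4 and 100 in striatum against cortex (19313 genes). Unchanged genes made up at most 5.1% of the calls.

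Alternatives planned before the data were examined were the DESeq2 Wald test, DESeq2's size factors in edgeR, no filter on low counts, a filter of 1 CPM in every library of a group, removal of the 1% of genes with the highest counts, leaving out each library in turn in comparisons with a group of up to 5 libraries, and settings specific to single comparisons. Added later were fits without the libraries that stand apart and fits limited to genes without copies. Other splits of the libraries were drawn with a fixed seed of 1, 100 for comparisons of up to 24 libraries and 50 for larger ones. The software was R 4.3.3, edgeR 4.0.16, DESeq2 1.42.0, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.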

Results

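The series is a set of bulk RNA-seq maps of healthy animal tissues from mouse, dog, cynomolgus monkey and rat, species used in nonclinical research. The labels divide 796 libraries by species, map and tissue or, in a few groups, isolated cell type. The mouse maps hold 158 libraries in 24 tissues of C57BL6, an inbred laboratory strain, and 168 libraries in 27 tissues of CD1, an outbred stock. The dog map holds 184 libraries in 45 tissues, and the second cynomolgus map holds 197 libraries in 38 tissues. An earlier cynomolgus map holds 52 single-end libraries in 37 groups and 15 paired-end libraries in 12 groups, and 3 small rat sets hold 16, 3 and 3 libraries. The labels give neither the sex nor the identity of the animals, so no libraries were paired, and p-values measure the spread between libraries, which may be partly technical.

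Total counts per library, the depth behind every value, varied by map. C57BL6 libraries held 25.51 to 47.38 M counts (median 41.72 M) and CD1 libraries 26.3 to 49.45 M (median 41.32 M). Dog libraries ranged from 3.95 to 128.55 M (median 38.89 M), second-map cynomolgus libraries from 30.12 to 76.16 M (median 40.66 M) and first-map single-end libraries from 0.02 to 160.21 M (median 22.02 M). The paired-end libraries of the first cynomolgus map held 7.25 to 23.14 M counts (median 12.11 M) and those of the largest rat set 35.6 to 42.52 M (median 39.22 M).

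**Figure D1:**
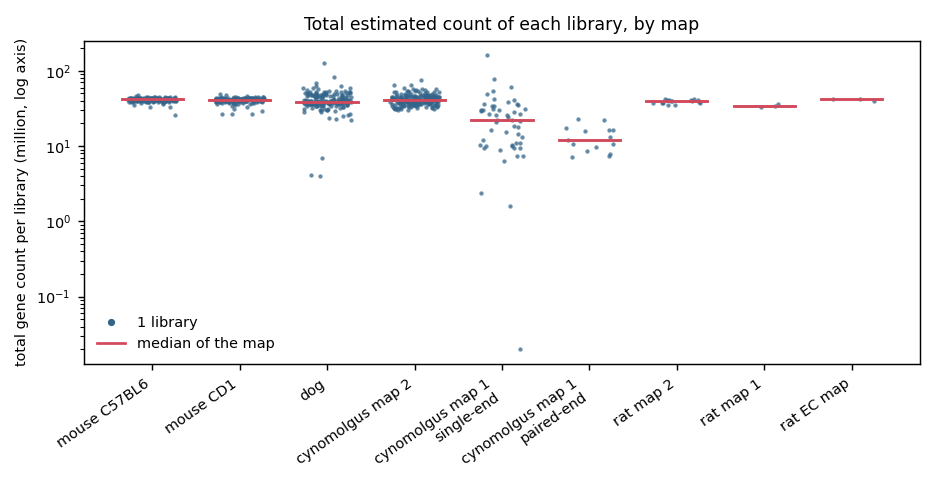
Total estimated count of each library in M counts (log axis) for each map, with a point per library and a line at the median of the map. The mouse libraries lie between 25.51 and 49.45 M, while the first-map single-end cynomolgus libraries reach from 0.02 to 160.21 M.

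Of 676 libraries in groups of at least 3, 586 had their nearest library in the same tissue. In 36 libraries the median correlation to their group lay more than 0.03 below that of the group, and 24 of these had their nearest library in another tissue. The library labelled C57BL6 hippocampus replicate 1 held the cardiac transcripts Myh6 (31000 CPM) and Nppa (17400 CPM), and its neuron markers stood at 0.498% of the other C57BL6 hippocampus libraries. The library labelled CD1 hippocampus replicate 3 held the intestinal transcripts Apoa1 (20000 CPM), Fabp2 (4040 CPM) and Alpi (2240 CPM), with neuron markers at 0.613%. In the 2 libraries labelled CD1 duodenum, which entered no comparison, the same neuron markers stood at 93.5% and 78.5%. All labelled libraries stayed in the comparisons. The numbers of called genes without the libraries that stood apart are given for the single comparisons in which they differed.

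**Figure D2:**
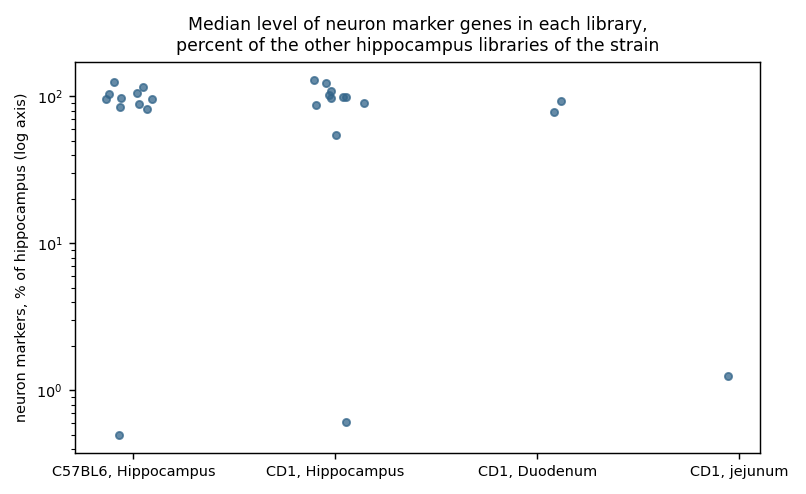
Median level of neuron marker genes in each hippocampus, duodenum and jejunum library, in percent of the other hippocampus libraries of the strain (log axis), with a point per library. A library of each strain labelled hippocampus lies at 0.498% and 0.613%, whereas the libraries labelled CD1 duodenum lie at 93.5% and 78.5%.

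The atlas comparison asked which genes mark single tissues. A gene counted as enriched when its lowest library in a tissue was at least 4 times the highest mean of any other tissue of the map and its mean reached 10 CPM. Liver held the most enriched genes of both mouse maps, 513 in C57BL6 and 609 in CD1, of which 455 were shared, and albumin (Alb) alone reached 133000 ± 35700 CPM (SD, n = 5) in C57BL6. Adrenal gland was marked by steroid synthesis genes, Cyp21a1 at 13000 ± 5180, Hsd3b1 at 8410 ± 2330 and Star at 6740 ± 1380 CPM (SD, n = 6). Pituitary was marked by its hormones, Gh at 106000 ± 23000, Prl at 70100 ± 46100 and Pomc at 14500 ± 3950 CPM (SD, n = 8). The hypothalamus held the neuropeptide genes Pmch at 293 ± 79.2, Avp at 291 ± 84.7 and Oxt at 156 ± 39.7 CPM (SD, n = 12). Cbln3, a cerebellar granule cell gene, stood at 1440 ± 181 CPM in cerebellum (SD, n = 12), and the natriuretic peptide gene Nppa at 27600 ± 5110 CPM in atrium (SD, n = 10). In striatum Adcy5 stood at 1410 ± 333 and Penk at 1200 ± 375 CPM (SD, n = 8). Outside liver, the enriched genes shared by the strains numbered 66 in mandibular salivary gland (79 in C57BL6, 96 in CD1), 31 in pituitary (47 and 37), 30 in cerebellum (38 and 35), 25 in skeletal muscle (38 and 32), 22 in adrenal gland (31 and 30), 12 in hypothalamus (17 and 15) and 11 in striatum (13 and 15). Few were shared in tongue (5 of 18 and 12), spinal cord (3 of 8 and 4), esophagus (1 of 4 and 24) and thyroid (0 of 4 and 0). Atrium held 66 enriched genes in C57BL6 and 18 in CD1, 14 of them shared. The C57BL6 ventricle, with 2 libraries, was not among the tissues compared. The next highest tissue for Nppa in C57BL6 was hippocampus, at a mean of 1630 CPM, a group that includes the library with cardiac transcripts. Without the libraries that stood apart, atrium held 74 enriched genes in C57BL6 and 18 in CD1. Thyroid then went from 4 to 30 in C57BL6 and from 0 to 36 in CD1, and tongue from 18 to 33 and from 12 to 47, while CD1 esophagus went from 24 to 15. Levels in this paragraph are scaled over all tissues of a map and differ from those of single comparisons, which are scaled within the comparison. Across the 4 largest maps, 5494 enriched genes were counted over 112 tissues. This definition has no test, and the number of tissue-enriched genes moved to 9761 at a 2-fold margin. It also depends on the tissues in a map. Neither mouse map holds testis or ovary, so a gene shared with a missing tissue can still count as enriched.

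The strain comparison asked how C57BL6 and CD1 differ in 9 tissues, chosen before the data were examined, with at least 4 libraries of each strain. Cerebellum, hippocampus, spinal cord, striatum, brown fat, esophagus and tongue also had that many and were not tested for strain. Fold changes are given as log2 of C57BL6 over CD1 with their standard errors, so negative values mark genes higher in CD1. Between 859 genes (muscle) and 4095 genes (pituitary) passed the test. Of 13394 genes tested in all 9 tissues, 7212 passed in at least 1 tissue, 3706 of them in a single one. Among the same 13394 genes, 93 differed in the same direction in all 9 tissues, against 1.58e-07 expected by chance from independent lists. Of these 93, 30 were higher in C57BL6 and 63 higher in CD1. Pttg1, which encodes securin, a regulator of chromosome separation, was higher in C57BL6 by 2.76 in liver to 4.86 in muscle, with a mean of 3.31. Other shared genes higher in C57BL6 included Ppp1r3e (mean 2.05), Isoc2b (mean 1.42), the tripartite motif genes Trim12a (mean 5.14) and Trim34a (mean 1.87), and the ribosomal protein genes Rps18 (mean 4.64), Rpl3 (mean 1.80), Rps7 (mean 1.53) and Rpl29 (mean 1.47). Alad, an enzyme of haem synthesis, was higher in CD1 with a mean of −1.01, as were Lyplal1 (mean −1.12), the flippase gene Atp10d (mean −1.11), Hddc3 (mean −1.56), Abhd1 (mean −3.23) and the histocompatibility gene H2-T10 (mean −2.96). Vcp-rs (mean −10.82) and Eno1b (mean −7.87), both higher in CD1, had the largest changes among the shared genes named here.

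Many of these genes share sequence with other genes of the annotation. A gene was counted as having copies when at least 10% of the 31-base words of its transcripts also occurred in another gene, on either strand. This threshold does not show a near-identical copy, and the partner need not be a related gene. For Nrn1 (20.55%) the partner was Fars2, and for Pmch (49.38%) it was Parpbp. Of the 90 shared genes with a reference sequence, 72 (80%) had copies, against 36.8% of 900 genes of matched level. When the counts of a shared gene and its closest copy were added, the median absolute log2 fold change over 68 pairs went from 4.96 to 0.15. In 39 of these pairs the copy made most of the sum, which by itself dilutes a change. In the other 29 the median went from 1.79 to 0.56 (31.6% left). In these sums, which use mean levels in place of the fit, Vcp-rs changed by −10.29 and its copy Vcp by 0.73, while their sum changed by −0.09. Rpl3 changed by 1.81 and the pseudogene Rpl3-ps1 by −10.93, while their sum changed by −0.07. The fold changes of genes with copies are therefore uncertain as statements on single genes, and the share of such sequence is given below, once for each gene, where it exceeded 10%. Among shared genes with less copied sequence were Pttg1, Ppp1r3e, Isoc2b, Lyplal1, Atp10d and Alad. Without genes that have copies, 1686 genes differed in cortex, 2043 in hypothalamus, 1850 in aorta, 1749 in thyroid, 548 in adrenal gland, 867 in liver and 475 in muscle, and 17 genes were shared.

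The strain difference itself varied between tissues. In a test of the interaction of strain and tissue over 160 libraries, 8778 of 27741 genes (31.6%) were called, and 1008 genes with a called interaction passed the strain test in opposite directions in different tissues. With strain labels redrawn within tissues, the same test called a median of 1218 genes and at most 2741. Cacna1h, a T-type calcium channel gene, was higher in C57BL6 atrium (4.56) and lower in C57BL6 thyroid (−1.51), with an interaction adjusted p of 5.25e-28. Eps8l1 was higher in C57BL6 muscle (4.91) and lower in C57BL6 thyroid (−1.12), with an adjusted p of 6.17e-25. Xist, transcribed from the inactive X chromosome, was called in no strain comparison by the edgeR test, and its cortex fold change was 0.37 ± 1.58 with an adjusted p of 0.913. Within each strain the Xist level of single cortex libraries ranged widely, from 0.023 to 774 CPM in C57BL6 and from 0.024 to 599 CPM in CD1. The 2 strains come from separate maps, so strain and map cannot be told apart here.

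Interferon-stimulated genes, transcripts induced by the antiviral interferons, had a median log2 fold change above 0 in each of the 9 tissues, from 0.36 in hypothalamus to 0.96 in liver. Most members were not called in hypothalamus, aorta, liver and muscle. The number of members called higher was 16 of 25 in cortex, 9 of 26 in hypothalamus, 21 of 26 in atrium, 8 of 26 in aorta, 20 of 26 in pituitary, 15 of 26 in thyroid, 16 of 26 in adrenal gland, 10 of 26 in liver and 7 of 25 in muscle. A single member was lower, Gbp2 in aorta at −0.56 ± 0.10. Usp18, which removes the ubiquitin-like Isg15, was called in all 9 tissues at 0.55 to 1.59. Gbp3 and Oasl2 were each called in 8 tissues, and Oas1a, Ifit1, Isg15 and Igtp in 7. Adjusted over the list alone, the members higher were 19, 13, 23, 12, 22, 20, 21, 18 and 11 in the same order of tissues, and those lower were 1 in cortex and 2 in aorta. The list test with the preset correlation gave adjusted p-values from 3.05e-20 (adrenal gland) to 0.00183 (aorta). With an estimated correlation none of the 9 passed, from adjusted p = 0.0593 in pituitary to adjusted p = 0.971 in hypothalamus. The median of macrophage markers lay between −0.46 in aorta and 0.40 in thyroid, that of T cell markers between −2.89 in atrium and 1.80 in thyroid, and that of B cell markers between −1.03 in aorta and 3.17 in thyroid. The atrium and thyroid groups each include a library with outlying lymphocyte transcripts, described with these tissues. Without the libraries that stood apart, the thyroid medians were 0.10, 1.45 and 0.48, beside 0.53 for the interferon list, of which 14 of 26 members were called (list adjusted p = 1.76e-06).

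**Figure D3:**
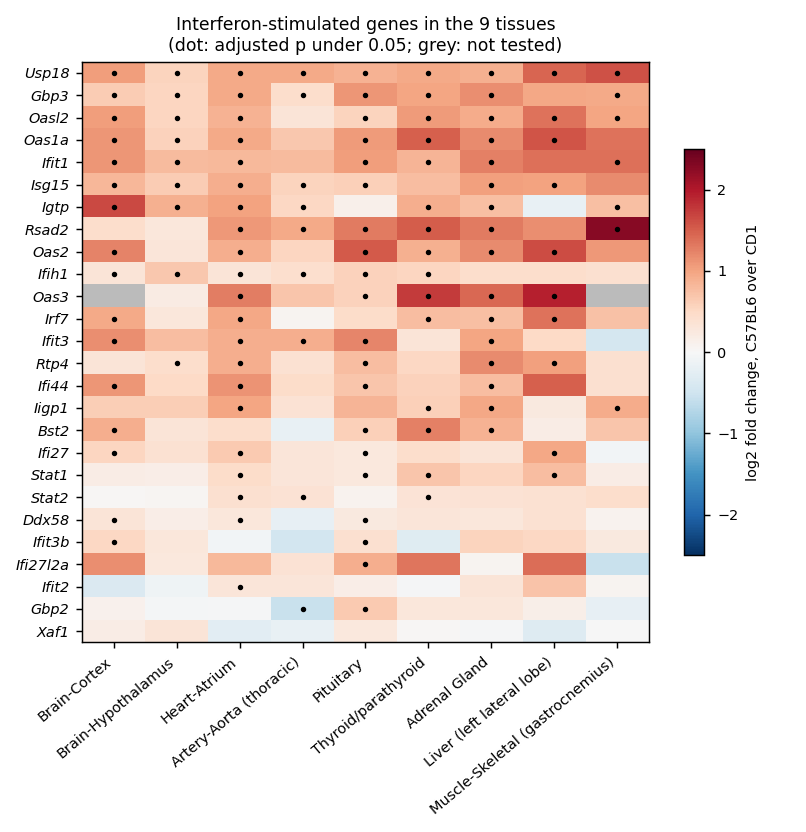
Log2 fold change, C57BL6 over CD1, of each interferon-stimulated gene (vertical axis) in each of the 9 tissues (horizontal axis), with a dot where the adjusted p passed and grey where a gene was not tested. Usp18 carries a dot in all 9 tissues, and the single called value below 0 is Gbp2 in aorta.

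In cerebral cortex (12 and 11 libraries), C57BL6 held more Myo7a, an unconventional myosin, at 27.2 ± 3.85 against 3.12 ± 0.487 CPM (SD), a change of 3.12 ± 0.10 (SE, adjusted p = 4.45e-19). Etnppl, an astrocyte enzyme of phospholipid metabolism, stood at 28.1 ± 15.7 against 4.15 ± 1.94 CPM (2.76 ± 0.29). CD1 held more of the phospholipase gene Pla2g4e, at 53.1 ± 10.8 against 10.7 ± 4 CPM (−2.31 ± 0.18), and more Cfap54, a ciliary gene (−1.84 ± 0.15). The chemokine gene Ccl19 stood at 35.9 ± 6.27 CPM in CD1 and 1.03 ± 0.285 CPM in C57BL6 (−5.12 ± 0.13), and 57.01% of its words occurred in another gene. Amd2 changed by −3.73 ± 0.31, with a share of 87.04%. Among interferon-stimulated genes Igtp (1.66 ± 0.16, share 15.6%), Oasl2 (1.05 ± 0.17), Bst2 (0.90 ± 0.16) and Isg15 (0.83 ± 0.15, share 19.05%) had the smallest p-values. Immediate early genes, the first to respond to neuronal activity, were higher in C57BL6 in 7 of 22 members and lower in none (14 adjusted over the list alone), including Nr4a3 (0.89 ± 0.18), Fosb (0.74 ± 0.19), Fosl2 (0.58 ± 0.15) and Nr4a1 (0.96 ± 0.28). The list test gave an adjusted p of 7.7e-06, lost at adjusted p = 0.884 with an estimated correlation, and Nr4a1 was lost without the filter on low counts (0.0582). Of 25 neurotransmitter receptor and transporter genes, 4 were lower in C57BL6, among them Htr1a (−0.53 ± 0.10) and Gabra2 (−0.69 ± 0.18), and 1 was higher, Gria1 (0.29 ± 0.07), with 5 and 1 adjusted over the list alone (list adjusted p = 0.0275, and adjusted p = 0.884 with an estimated correlation). Of 15 GABAergic interneuron markers, Adarb2 (−0.86 ± 0.11) and Vip (−0.41 ± 0.10) were lower, 3 adjusted over the list alone (list adjusted p = 0.0365, and adjusted p = 0.261 with an estimated correlation). The edgeR test called 2596 of 19031 genes, 1416 higher and 1180 lower in C57BL6.

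In hypothalamus (12 libraries each), Rec8, a meiotic cohesin gene, was higher in C57BL6 at 18 ± 3.57 against 0.848 ± 0.428 CPM (SD), a change of 4.40 ± 0.22 (SE). Eps8l1 followed at 10.5 ± 4.05 against 1.09 ± 0.314 CPM (3.27 ± 0.19), and Myo7a changed by 2.73 ± 0.07. Higher in CD1 were Pla2g4e at 38.2 ± 6 against 6.32 ± 1.49 CPM (−2.60 ± 0.11), the protein-citrullinating enzyme Padi2 at 136 ± 27.5 against 42 ± 6.68 CPM (−1.69 ± 0.11) and Card10 (−1.48 ± 0.11). The leading interferon-stimulated genes were Igtp (0.88 ± 0.10), Ifih1 (0.67 ± 0.12) and Ifit1 (0.79 ± 0.15). Heat shock and glucocorticoid-responsive genes were higher in 5 and lower in 2 of 20 members (11 and 3 adjusted over the list alone). Hspa8 changed by 0.90 ± 0.07, Hspa1a by 1.05 ± 0.13 and Hspe1 by 0.67 ± 0.15, and these chaperone genes had 46.58%, 65.22% and 28.41% of their words in other genes. The list test gave an adjusted p of 0.0205, and adjusted p = 0.971 with an estimated correlation. Of 25 receptor and transporter genes 2 were lower, including Gabra2 (−0.75 ± 0.20), and Gria1 was higher (0.30 ± 0.05), the same numbers as adjusted over the list alone (list adjusted p = 0.0427, and adjusted p = 0.971 with an estimated correlation). In all, 3198 of 19404 genes were called, 1693 higher and 1505 lower in C57BL6.

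In atrium (10 and 9 libraries), the calcium channel gene Cacna1h stood at 258 ± 72.9 CPM in C57BL6 and 11 ± 11 CPM in CD1 (SD), a change of 4.56 ± 0.47 (SE, adjusted p = 6.2e-07). Lmntd1 stood at 137 ± 18 against 6.74 ± 7.1 CPM (4.35 ± 0.56), the Wnt antagonist gene Sfrp5 at 92.3 ± 32.5 against 10.8 ± 9.38 CPM (3.09 ± 0.41) and the cytokine gene Il15 at 25.8 ± 5 against 4.13 ± 1.92 CPM (2.64 ± 0.21). Myh7, the slow myosin heavy chain, stood at 1370 ± 361 CPM in CD1 and 52.8 ± 19.9 CPM in C57BL6 (−4.69 ± 0.26), with 28.78% of its words in another gene. Hist1h2al (−8.03 ± 0.65), H2-Q1 (−6.36 ± 1.01) and H2-Q2 (−5.36 ± 0.55) were also higher in CD1 and had shares of 78.95%, 22.86% and 28.57%. The leading interferon-stimulated genes were Gbp3 (0.94 ± 0.10), Irf7 (0.96 ± 0.13), Rtp4 (0.90 ± 0.12, share 10.61%) and Ifit1 (0.82 ± 0.11). Immediate early genes went the other way than in cortex, with 11 of 20 lower and 1 higher in C57BL6, the same adjusted over the list alone. Egr1 stood at 51.3 ± 18.3 against 271 ± 293 CPM (−2.40 ± 0.52), and Junb (−1.81 ± 0.33), Btg2 (−1.88 ± 0.38) and Ier2 (−1.56 ± 0.36) were lower too (list adjusted p = 0.00792, and adjusted p = 0.994 with an estimated correlation). Cell cycle genes were lower in 10 of 24 members (14 lower and 1 higher adjusted over the list alone), including Ccnb1 (−2.14 ± 0.41, share 25.29%), Cdk1 (−1.51 ± 0.36) and Ube2c (−1.80 ± 0.43, share 26.07%), with a list adjusted p of 0.00844 and adjusted p = 0.994 with an estimated correlation. The T cell gene Cd8a changed by −4.23 ± 1.24 (adjusted p = 0.0228), but CD1 replicate 8 held 131 CPM and the next highest CD1 library 1.12 CPM, and DESeq2 gave 0.43. In atrium 3257 of 17852 genes were called, 1572 higher and 1685 lower in C57BL6.

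In thoracic aorta (12 and 9 libraries), C57BL6 held more Rab6b, a vesicle transport gene, at 45 ± 13.9 against 6.02 ± 4.66 CPM (SD; 2.90 ± 0.38, SE), and more Fbxo44 at 14.4 ± 4.64 against 2.83 ± 1.08 CPM (2.34 ± 0.22). The complement gene C1rb changed by −9.43 ± 0.76, with 70.83% of its words in another gene. Cholesterol synthesis genes were higher in C57BL6 in 8 of 21 members (11 adjusted over the list alone), led by Sc5d (1.34 ± 0.18), Fdps (1.11 ± 0.26, share 27.75%) and Nsdhl (1.34 ± 0.32), with a list adjusted p of 0.00183 and adjusted p = 0.867 with an estimated correlation. Brown adipocyte markers were higher in 3 of 9 members (4 adjusted over the list alone): the fatty acid elongase Elovl3 (5.24 ± 0.80), the deiodinase Dio2 (2.14 ± 0.42) and the coactivator Ppargc1a at 42.8 ± 20 against 20.6 ± 6.05 CPM (1.05 ± 0.23), with a list adjusted p of 0.00687 and adjusted p = 0.867 with an estimated correlation. Heat shock genes were higher in 4 of 20 (5 adjusted over the list alone), including Hspa8 (0.92 ± 0.17) and Hsp90aa1 (0.69 ± 0.15, share 51.39%), with a list adjusted p of 0.0093 and adjusted p = 0.867 with an estimated correlation. Major histocompatibility genes were lower in 10 and higher in 2 of 30 members (11 and 2 adjusted over the list alone), with H2-T10 at −3.67 ± 0.25, H2-Bl at −7.10 ± 0.56 and H2-Q1 at −6.46 ± 0.52 (shares 66.4%, 21.85% and 22.86%, list adjusted p = 0.00476, and adjusted p = 0.867 with an estimated correlation). Immediate early genes were lower in 5 of 21 (7 adjusted over the list alone), including Zfp36 (−0.96 ± 0.18) and Egr1 (−1.49 ± 0.30), and 1 was higher, Nr4a2 (1.69 ± 0.35), with a list adjusted p of 0.0123 and adjusted p = 0.867 with an estimated correlation. Cell cycle genes were lower in 3 of 24 in both counts, among them Cdk1 (−0.94 ± 0.26) and Birc5 (−1.23 ± 0.37), with a list adjusted p of 0.0174 and adjusted p = 0.867 with an estimated correlation. Among interferon-stimulated genes Rsad2 (0.94 ± 0.20) and Usp18 (0.94 ± 0.21) were higher. CD1 replicate 3 and C57BL6 replicate 6 stood apart from their groups. Without them the brown adipocyte count was 4 of 9 and the cholesterol synthesis count 11 of 21 higher and 1 lower. Skeletal muscle markers, with 0 of 14 called over all libraries (list adjusted p = 0.185), were then lower in 11 of 14 (list adjusted p = 0.0647). Conjugation and transporter genes went from 7 of 22 lower and 1 higher (list adjusted p = 0.117) to 9 of 23 lower and 3 higher (list adjusted p = 0.0461). Of 18246 genes tested in aorta 2845 were called, 1276 higher and 1569 lower in C57BL6. Without both libraries 4076 were called, 1900 higher and 2176 lower.

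In pituitary (8 libraries each), 2 of 10 hormone genes were lower and 1 higher in C57BL6, the same adjusted over the list alone, and the list did not pass (adjusted p = 0.666). Pomc, the precursor of corticotropin, stood at 18100 ± 4670 CPM in C57BL6 and 45000 ± 11800 CPM in CD1 (SD; −1.31 ± 0.19, SE, adjusted p = 0.000112). Gh, growth hormone, stood at 132000 ± 26300 against 185000 ± 47500 CPM (−0.49 ± 0.16, adjusted p = 0.0385, lost at 0.104 without the filter on low counts). C57BL6 held more of the protocadherin gene Pcdh20 at 14.3 ± 3.35 against 1.8 ± 0.848 CPM (2.99 ± 0.26), Rab6b at 63.2 ± 5.3 against 9.38 ± 11.5 CPM (2.76 ± 0.45), Rec8 (3.78 ± 0.21) and Kctd4 (2.41 ± 0.41). CD1 held more of the amino acid transaminase gene Bcat1 at 88.2 ± 20.3 against 11.4 ± 1.74 CPM (−2.95 ± 0.15), of Nrn1 (−3.99 ± 0.25, share 20.55%) and of Tpm3-rs7 (−8.54 ± 0.35, share 76.54%). Cholesterol synthesis genes were lower in C57BL6 in 15 of 21 members (17 adjusted over the list alone), including Dhcr7 (−0.46 ± 0.06) and the sterol sensor gene Insig1 (−0.46 ± 0.08), with a list adjusted p of 3.57e-06 and adjusted p = 0.563 with an estimated correlation. Major histocompatibility genes were higher in 15 and lower in 6 of 30 (16 and 6 adjusted over the list alone), with H2-Eb2 at 6.37 ± 0.39, H2-T22 at 1.19 ± 0.09 (share 68.23%) and H2-T10 at −2.06 ± 0.12 (list adjusted p = 0.00191, and adjusted p = 0.563 with an estimated correlation). Choroid plexus and ependymal markers were lower in 5 of 10 (6 adjusted over the list alone), including Kl (−0.69 ± 0.09), Slc4a5 (−1.46 ± 0.21) and Foxj1 (−0.71 ± 0.13), with a list adjusted p of 0.00666 and adjusted p = 0.0593 with an estimated correlation. Among interferon-stimulated genes Rsad2 changed by 1.29 ± 0.16. In all, 4095 of 19906 genes were called, 1871 higher and 2224 lower in C57BL6.

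In thyroid with parathyroid (12 libraries each), the hormone receptor gene Cckar stood at 11.2 ± 4.96 CPM in C57BL6 and 0.645 ± 0.31 CPM in CD1 (SD; 4.11 ± 0.38, SE). The hexose transporter gene Slc2a6 stood at 11.6 ± 5.08 against 1.22 ± 0.454 CPM (3.25 ± 0.27) and the lipase gene Pnpla3 at 38.3 ± 39.2 against 7.04 ± 2.69 CPM (2.44 ± 0.33), and Rab6b changed by 3.31 ± 0.14. Adipocyte markers were higher in C57BL6 in 10 of 12 members (11 adjusted over the list alone), among them the adipokine gene Cfd at 1830 ± 2980 against 389 ± 112 CPM (2.23 ± 0.45), the lipid droplet gene Plin1 at 214 ± 158 against 93 ± 29.8 CPM (1.21 ± 0.25) and Adrb3 (1.76 ± 0.39, share 24.6%), with a list adjusted p of 2.3e-06 and adjusted p = 0.779 with an estimated correlation. Brown adipocyte markers were higher in 4 of 10 in both counts, with the uncoupling protein gene Ucp1 at 324 ± 206 against 93.9 ± 51.8 CPM (1.79 ± 0.40), Dio2 (1.55 ± 0.16) and Elovl3 (2.09 ± 0.41), a list adjusted p of 0.00259 and adjusted p = 0.0688 with an estimated correlation. C57BL6 replicate 9 held 11200 CPM of Cfd, 705 CPM of Plin1 and 897 CPM of Ucp1, against next highest values of 1670, 258 and 470 CPM. This library and CD1 replicate 8 stood apart from their groups, and without them the counts were again 10 of 12 and 4. The B cell gene Cd79a (46 ± 154 against 0.898 ± 0.702 CPM, 5.68 ± 1.30, share 13.59%) rested on replicate 9 as well, where it reached 536 CPM against 2.95 CPM in the next library. Without both libraries Cd79a changed by 0.69 (adjusted p = 0.216). The B cell list, with 7 of 9 members called including Fcrla (3.89 ± 0.80), did not pass (adjusted p = 0.0999). Without both libraries 1 of 9 was called (list adjusted p = 0.356), and Fcrla changed by 1.76 (adjusted p = 0.00118). The T cell list, with 2 of 11 members called and 5 adjusted over the list alone (list adjusted p = 0.0199, and adjusted p = 0.939 with an estimated correlation), then had 0 called (list adjusted p = 0.131). Major histocompatibility genes were higher in 19 and lower in 4 of 29 members (21 and 4 adjusted over the list alone), with H2-K2 lower at −5.80 ± 0.59 (share 17.41%), a list adjusted p of 4.17e-05 and adjusted p = 0.917 with an estimated correlation. Circadian clock genes were lower in 9 and higher in 1 of 19 (11 and 2 adjusted over the list alone), including Hlf (−1.30 ± 0.22), Cipc (−0.35 ± 0.08) and Per3 at 14.2 ± 7.28 against 47.3 ± 26.6 CPM (−1.73 ± 0.33), with a list adjusted p of 0.0199, adjusted p = 0.917 with an estimated correlation, and 0.131 without the libraries standing apart. Of 14 thyroid follicular genes 1 was higher, and 0 adjusted over the list alone (list adjusted p = 0.697). Without the libraries standing apart 4 were higher and 1 lower (list adjusted p = 0.209). Interferon-stimulated genes were led by Oas1a (1.49 ± 0.22, share 63.81%), Gbp3 (0.99 ± 0.15) and Rsad2 (1.51 ± 0.24). In thyroid 2633 of 18826 genes were called, 1387 higher and 1246 lower in C57BL6. Without the libraries standing apart 3642 were called, and more of them were lower (1977) than higher (1665).

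In adrenal gland (6 and 7 libraries), the kinase gene Nek5 stood at 18 ± 10.5 CPM in C57BL6 and 0.421 ± 0.221 CPM in CD1 (SD; 5.40 ± 0.50, SE), Eps8l1 at 10.5 ± 3.96 against 0.37 ± 0.15 CPM (4.81 ± 0.37) and Rec8 at 45 ± 7.91 against 2.5 ± 1.14 CPM (4.17 ± 0.35). Kpna2 changed by 4.98 ± 0.72, with 62.25% of its words in another gene. Cfap54 was higher in CD1 at 45.8 ± 11.3 against 1.65 ± 1.04 CPM (−4.79 ± 0.34). Of 16 adrenal cortex markers 1 was lower in C57BL6 (2 adjusted over the list alone, list adjusted p = 0.115), Cyp11a1, the first enzyme of steroid synthesis, at 6030 ± 712 against 8300 ± 1200 CPM (−0.46 ± 0.12, adjusted p = 0.0409), and its call was lost (0.052) when genes with copies were left out of the test. Brown adipocyte markers were higher in 3 of 8 (6 adjusted over the list alone), including Dio2 (2.80 ± 0.50), with a list adjusted p of 1.51e-06 and adjusted p = 0.393 with an estimated correlation. Schwann cell markers were higher in 3 of 9 (4 adjusted over the list alone), including Sox10 (1.05 ± 0.25), with a list adjusted p of 0.0042 and adjusted p = 0.393 with an estimated correlation. Major histocompatibility genes were higher in 8 and lower in 4 of 29 (11 and 5 adjusted over the list alone), with a list adjusted p of 0.0042 in the upward direction, a median of 0.37 and a mean of −0.28, and adjusted p = 0.575 with an estimated correlation. Conjugation and transporter genes were lower in 3 of 24 in both counts, including Ugt1a6a (−1.28 ± 0.23, share 51.51%), with a list adjusted p of 0.0488 and adjusted p = 0.575 with an estimated correlation. Ifit1 (1.26 ± 0.11), Rsad2 (1.30 ± 0.14) and Gbp3 (1.16 ± 0.12) led the interferon-stimulated genes. With edgeR 1100 of 18775 genes were called, 521 higher and 579 lower, and DESeq2 called 1779. Another split of the same adrenal libraries, across the strains, called 2557 genes.

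In liver (5 and 4 libraries), drug-metabolising genes of the cytochrome P450 family were lower in C57BL6 in 4 of 36 members (4 lower and 1 higher adjusted over the list alone), including Cyp2d22 at 225 ± 46.2 against 456 ± 76.1 CPM (SD; −1.02 ± 0.17, SE) and Cyp2c39 (−6.93 ± 0.98, share 30.77%), and the list did not pass (adjusted p = 0.992). Cholesterol synthesis genes were lower in 5 of 22 (9 adjusted over the list alone), with Dhcr7 at −0.72 ± 0.13, Fdft1 at −0.65 ± 0.12 (share 28.99%) and Lss at −0.72 ± 0.13, a list adjusted p of 0.00156 and adjusted p = 0.78 with an estimated correlation. Pctp, a phosphatidylcholine transfer protein gene, was higher in C57BL6 at 143 ± 24.7 against 10.7 ± 9.48 CPM (3.74 ± 0.75, adjusted p = 0.019), a call lost at 0.0539 without CD1 replicate 1. Major urinary protein genes, a family of near-identical copies, went both ways, with 2 of 21 higher and 4 lower (6 and 5 adjusted over the list alone, list adjusted p = 0.992). Mup5 (−4.41 ± 0.49), Mup2 (−6.27 ± 0.82) and Mup9 (−4.52 ± 0.63) had shares of 36.45%, 76.71% and 89.56%. Mup19 (6.21 ± 1.44, adjusted p = 0.0346, share 100%) was lost in 8 of 9 fits that left out 1 library, at up to 0.0924, and kept only without CD1 replicate 4. Serpina1e changed by 5.14 ± 0.79 (share 55.02%), and the complement genes C1rb by −8.97 ± 0.35 and C1s2 by −8.95 ± 0.46 (shares 70.83% and 43.37%), and H2-Q2 by −7.10 ± 1.16. Irf7 (1.36 ± 0.22), Oas1a (1.58 ± 0.28) and Oasl2 (1.36 ± 0.26) led the interferon-stimulated genes. With edgeR 1465 of 15883 liver genes were called, 635 higher and 830 lower, and DESeq2 called 2388. Without C57BL6 replicate 1 the count was 903, without C57BL6 replicate 2 it was 952 and without CD1 replicate 1 it was 971.

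In gastrocnemius muscle (5 and 6 libraries), C57BL6 held more Rab6b at 12 ± 4.1 against 0.643 ± 0.191 CPM (SD; 4.22 ± 0.26, SE), more of the phosphatase gene Dusp26 at 38.9 ± 15.3 against 7.64 ± 2.34 CPM (2.35 ± 0.27) and more Myhas (3.05 ± 0.19, share 18.7%). CD1 held more of the methyltransferase gene Mettl21e at 41.3 ± 15.4 against 4.23 ± 2.85 CPM (−3.28 ± 0.47), of Kbtbd12 at 186 ± 29.9 against 36.2 ± 6.74 CPM (−2.36 ± 0.15), of Tmem37 (−1.71 ± 0.22) and of Ccl19 (−3.99 ± 0.48). Heat shock and glucocorticoid-responsive genes were higher in C57BL6 in 4 of 20 (7 higher and 1 lower adjusted over the list alone), including Hspa8 (1.01 ± 0.12) and Dnajb1 (0.50 ± 0.10, lost at 0.0579 without the filter on low counts), with a list adjusted p of 0.0029 and adjusted p = 0.182 with an estimated correlation. Immediate early genes were higher in 3 of 20 (5 adjusted over the list alone), including Nr4a1 (0.57 ± 0.11), with a list adjusted p of 0.013 and adjusted p = 0.852 with an estimated correlation. Usp18 (1.59 ± 0.31), Rsad2 (2.28 ± 0.48) and Ifit1 (1.37 ± 0.29) led the interferon-stimulated genes. With edgeR 859 of 16119 muscle genes were called, 430 higher and 429 lower, and DESeq2 called 1386. Without C57BL6 replicate 3, the library whose tissue label is spelled differently, the count was 568.

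**Figure D4:**
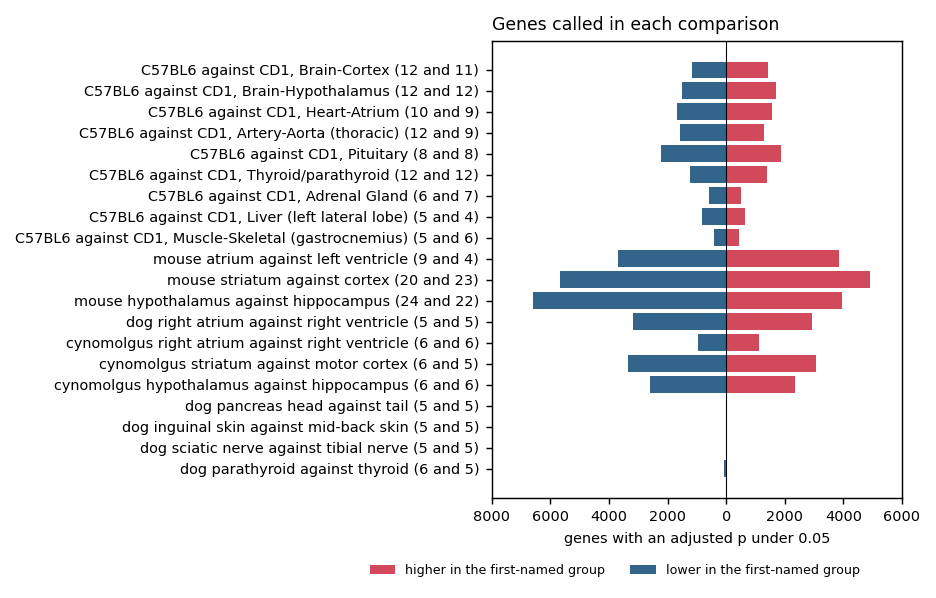
Number of genes with an adjusted p under 0.05 in each comparison, with genes higher in the first-named group to the right and lower to the left, and the libraries of both groups in brackets. Strain comparisons call 859 to 4095 genes, while striatum against cortex calls 10560 and the dog pancreas, skin and nerve comparisons call 0.

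The chamber comparison set CD1 atrium (9 libraries) against CD1 left ventricle (4 libraries). Atrium expressed its own contractile genes, with the sarcolipin gene Sln at 1860 ± 326 against 1.58 ± 0.971 CPM (SD; 10.19 ± 0.43, SE), the atrial light chain Myl7 at 4730 ± 1120 against 5.29 ± 5.58 CPM (9.80 ± 0.70) and Myl4 at 7210 ± 1270 against 9.23 ± 6.3 CPM (9.61 ± 0.48). Mybphl (9.54 ± 0.44), Tmem163 (8.43 ± 0.23), Mlana (7.71 ± 0.53), Sbk3 (7.63 ± 0.28) and Hamp (8.94 ± 1.22, share 30.65%) completed the 8 atrial genes named by the rule. Ventricle expressed the light chains Myl2 at 7300 ± 683 against 57.1 ± 101 CPM (−7.00 ± 1.55) and Myl3 at 6670 ± 810 against 111 ± 122 CPM (−5.91 ± 0.64), and the transcription factor gene Irx4 at 52.1 ± 3.57 against 0.346 ± 0.703 CPM (−7.24 ± 0.91). Acta1 (−6.49 ± 0.47), Rtn4r (−6.12 ± 0.54), Plekhh1 (−6.02 ± 0.24, share 13.8%) and Myh7b (−5.65 ± 0.55) were also higher in ventricle.

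Of 20 atrial myocardium markers 18 were higher in atrium (19 adjusted over the list alone), including Stard10 (4.79 ± 0.12), Sbk2 (5.69 ± 0.22) and Pam (3.27 ± 0.14), and 1 was lower, the potassium channel gene Kcna5 (−0.97 ± 0.32, adjusted p = 0.0248), a call lost at 0.0599 without the filter on low counts and at 0.0882 without ventricle replicate 1. Of 19 ventricular markers 16 were lower in atrium, including Fhl2 (−3.40 ± 0.11), Smyd2 (−3.99 ± 0.16, share 30.13%) and Lbh (−3.82 ± 0.21), and 1 was higher, Corin (1.00 ± 0.15), which cleaves the natriuretic propeptide, with the same counts adjusted over the list alone. Both lists passed, at 1.45e-16 and 1.72e-11, and held with an estimated correlation (adjusted p = 0.00133 and adjusted p = 0.0376). Fatty acid oxidation genes were lower in atrium in 19 of 20 members in both counts, with the trifunctional protein gene Hadhb at 750 ± 101 against 2820 ± 168 CPM (−1.91 ± 0.10, share 23.95%) and Acadm at −1.61 ± 0.10 (list adjusted p = 4.16e-17, and adjusted p = 0.166 with an estimated correlation). All 20 oxidative phosphorylation genes were lower in both counts, including Sdha (−1.11 ± 0.09) and Uqcrc2 (−1.16 ± 0.10, share 22.44%), with a list adjusted p of 1.72e-11 and adjusted p = 0.304 with an estimated correlation. All 12 epicardial and mesothelial markers were higher in atrium in both counts, including Krt19 (3.79 ± 0.40), Bnc1 (3.97 ± 0.50) and Msln (3.85 ± 0.48), as were 15 of 20 extracellular matrix genes (18 adjusted over the list alone), including Fbln1 (2.49 ± 0.21) and Col3a1 (1.56 ± 0.19). These 2 lists passed at 6.24e-07 and 1.18e-06 and were lost at adjusted p = 0.304 with an estimated correlation. Of 24 ion channel and calcium handling genes 13 were lower and 4 higher in atrium in both counts. The pacemaker channel gene Hcn2 changed by −2.94 ± 0.14, the L-type calcium channel gene Cacna1c by −1.89 ± 0.12, the potassium channel subunit genes Kcne1 by −3.80 ± 0.30 and Kcnj3 by 3.60 ± 0.19 (share 30.75%), with a list adjusted p of 0.0151 and adjusted p = 0.488 with an estimated correlation. Between the mouse chambers 7568 of 18590 genes were called, 3862 higher and 3706 lower in atrium.

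**Figure D5:**
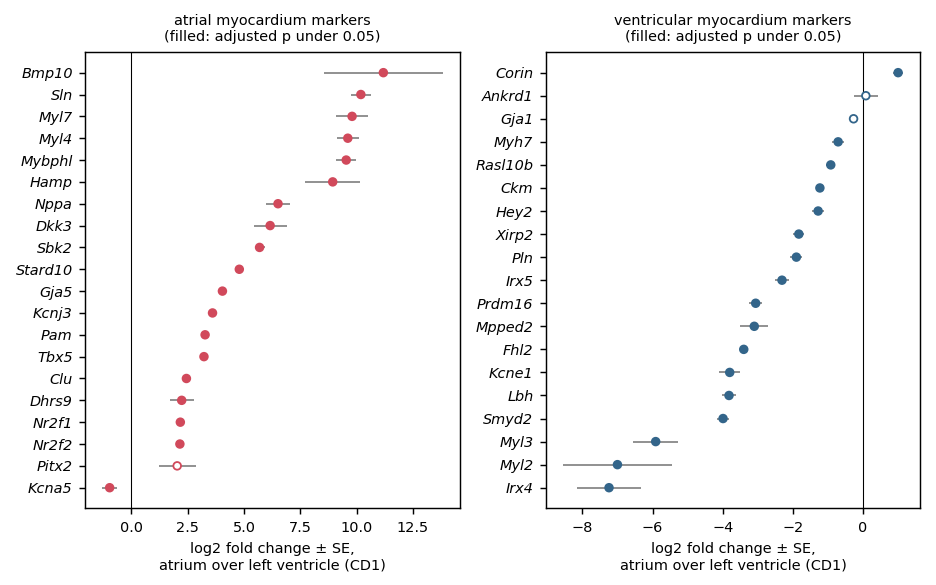
Log2 fold change ± SE of CD1 atrium over left ventricle for each atrial (left) and ventricular (right) myocardium marker, filled where the adjusted p passed. Atrial markers lie above 0 except Kcna5 at −0.97, and called ventricular markers below 0 except Corin at 1.00.

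Right atrium and right ventricle were compared in dog and cynomolgus monkey, for which the sources used here pair no gene names with the identifiers. In dog (5 libraries each), ENSCAFG00845028634 stood at 6700 ± 1200 CPM in ventricle and 16.2 ± 18.5 CPM in atrium (SD; −8.69 ± 1.03, SE) and ENSCAFG00845024941 at 28.9 ± 6.52 against 0.123 ± 0.107 CPM (−7.76 ± 0.45). ENSCAFG00845023837 (12.20 ± 1.86) and ENSCAFG00845018088 (10.18 ± 0.53) were higher in atrium. The edgeR test called 6131 of 16522 dog genes, 2947 higher and 3184 lower in atrium. In monkey (6 libraries each), ENSMFAG00000034420 stood at 191 ± 76.6 CPM in atrium against 0.137 ± 0.0994 CPM in ventricle (10.48 ± 0.62), and ENSMFAG00000036782 at 9170 ± 4640 CPM in ventricle against 9.71 ± 8.79 CPM (−9.88 ± 1.00). ENSMFAG00000035965 changed by 9.04 ± 1.11 and ENSMFAG00000000456 by −10.66 ± 1.00. The test called 2095 of 18942 monkey genes, 1128 higher and 967 lower in atrium. Replicate 6 of each chamber stood apart, each nearest to the other (r = 0.95), and without them 3758 genes were called, 1904 higher and 1854 lower. Adding the first-map single-end libraries, with map in the model, gave 3970.

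Striatum was compared with cortex in both mouse strains (20 and 23 libraries, strain in the model). Striatum expressed receptors and signalling genes of its projection neurons, with the adenosine receptor gene Adora2a at 516 ± 158 against 10.8 ± 19.3 CPM (SD; 5.69 ± 0.45, SE) and the dopamine receptor gene Drd2 at 344 ± 77 against 8.04 ± 18.4 CPM (5.66 ± 0.54). Serpina9 (5.91 ± 0.50), Isl1 (5.86 ± 0.44), Six3 (5.71 ± 0.53), Lrrc10b (5.67 ± 0.48) and Syndig1l (5.49 ± 0.46) had changes of similar size. Cortex held more of the zinc transporter gene Slc30a3 at 148 ± 24.4 against 24.4 ± 26.1 CPM (−2.67 ± 0.39), the neurotrophin gene Bdnf at 22 ± 6.27 against 4.52 ± 3.56 CPM (−2.32 ± 0.30, share 14.73%) and the neuropeptide gene Adcyap1 at 16.2 ± 4.76 against 2.32 ± 2.41 CPM (−2.94 ± 0.35). Nrn1 (−2.52 ± 0.34), Wnt10a (−2.39 ± 0.23), Cbln2 (−2.34 ± 0.33), Neurod2 (−2.11 ± 0.32) and Mkx (−2.11 ± 0.18) were also higher in cortex. All 20 striatal projection neuron markers were higher in striatum in both counts, including Pde1b (3.21 ± 0.12), Adcy5 (3.01 ± 0.14) and Arpp21 (1.74 ± 0.08), with a list adjusted p of 3.51e-28 and adjusted p = 0.0694 with an estimated correlation. Cortical glutamatergic markers were lower in 17 and higher in 2 of 20 in both counts, with Lamp5 at −1.20 ± 0.12, Camk2a at −1.03 ± 0.10 and Tle4 at 0.98 ± 0.09 (list adjusted p = 1.14e-06, and adjusted p = 0.534 with an estimated correlation). All 11 oligodendrocyte markers, including Aspa (0.95 ± 0.13) and Mog (1.05 ± 0.16), and all 11 choroid plexus and ependymal markers, including Clic6 (4.11 ± 0.29), Otx2 (3.44 ± 0.37), Ttr (5.30 ± 0.64) and Foxj1 (1.46 ± 0.14), were higher in striatum in both counts. These lists passed at 8.89e-05 and 0.000144 and were lost at adjusted p = 0.562 and adjusted p = 0.534 with an estimated correlation. The edgeR test called 10560 of 19503 genes, 4897 higher and 5663 lower in striatum. In monkey (6 and 5 libraries), striatum against motor cortex gave 6435 of 21758 genes, 3071 higher and 3364 lower. ENSMFAG00000039305 stood at 50.1 ± 7.9 against 0.0688 ± 0.075 CPM (9.61 ± 0.47) and ENSMFAG00000063427 at 0.111 ± 0.0683 against 46.9 ± 15.1 CPM (−8.71 ± 0.39). ENSMFAG00000059333 changed by 8.66 ± 0.30 and ENSMFAG00000053982 by −8.76 ± 0.56.

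Hypothalamus was compared with hippocampus in both mouse strains (24 and 22 libraries, strain in the model). Hypothalamus expressed its neuropeptides, with the orexin gene Hcrt at 128 ± 38.4 against 0.53 ± 2.06 CPM (SD; 8.29 ± 0.67, SE), Pmch, which encodes melanin-concentrating hormone, at 339 ± 74.5 against 2.37 ± 10 CPM (8.04 ± 0.83, share 49.38%) and the vasopressin gene Avp at 360 ± 124 against 1.85 ± 5.6 CPM (7.83 ± 0.61, share 21.88%). The developmental transcription factor gene Otp stood at 53.9 ± 13.6 against 0.431 ± 1.39 CPM (7.10 ± 0.54), and Bsx (7.38 ± 0.32), Calcr (7.26 ± 0.58), Fezf1 (7.11 ± 0.46) and Sim1 (7.04 ± 0.46) were of similar size. Hippocampus held more Smoc2 at 52.3 ± 31.7 against 3.03 ± 1.14 CPM (−4.11 ± 0.21), and more Dsp at 124 ± 255 against 3.11 ± 2.22 CPM (−5.38 ± 0.45, and −4.38 without the libraries that stood apart). Also higher in hippocampus were Wipf3 (−4.66 ± 0.20), Il16 (−4.15 ± 0.18, share 15.42%) and the prostaglandin synthase gene Ptgs2 (−4.23 ± 0.22). The naming rule needs groups without overlap, so it passes over genes absent from the 2 hippocampus libraries with cardiac and intestinal transcripts. Neurod6 stood at 0.0517 and 0 CPM there, so the genes named by the rule are not the largest changes toward hippocampus. Of 21 hypothalamic neuropeptide and regulator genes 19 were higher in both counts, including Hdc (4.18 ± 0.20), Nkx2-1 (5.25 ± 0.28) and Magel2 (5.17 ± 0.31), with a list adjusted p of 5.64e-26 that held with an estimated correlation (adjusted p = 0.00301). Cortical glutamatergic markers were lower in 17 and higher in 2 of 20, including Rtn4rl2 (−6.73 ± 0.33), Emx1 (−6.25 ± 0.40), Neurod6 (−6.63 ± 0.43) and Neurod2 (−6.41 ± 0.43), and hippocampal markers lower in 14 and higher in 1 of 16, including Spink8 (−5.73 ± 0.40) and Dkk3 (−2.40 ± 0.18), in both counts. These lists passed at 3.02e-05 and 0.000167 and were lost at adjusted p = 0.753 and adjusted p = 0.67 with an estimated correlation. All 11 microglia and macrophage markers were lower in both counts, including Tmem119 (−0.65 ± 0.07), Cd68 (−0.79 ± 0.10) and Csf1r (−0.58 ± 0.08, share 12.78%), with a list adjusted p of 0.00201 and adjusted p = 0.238 with an estimated correlation. Pituitary hormone markers were higher in 4 of 8 in both counts, including Pomc (4.20 ± 0.45) and Tbx19 (5.47 ± 0.38), with a list adjusted p of 0.0363, adjusted p = 0.67 with an estimated correlation, and 0.373 without the libraries that stood apart. The edgeR test called 10533 of 19598 genes, 3950 higher and 6583 lower, around a median of −0.135. The hippocampus groups include the 2 libraries with cardiac and intestinal transcripts, and without them 6624 genes were higher and 6212 lower (51.6% higher, against 37.5% with them), while DESeq2 on all libraries gave 5353 and 5462 (49.5%). In monkey (6 libraries each), 4954 of 21321 genes were called, 2366 higher and 2588 lower in hypothalamus. ENSMFAG00000039947 stood at 358 ± 333 against 0.0612 ± 0.109 CPM (12.49 ± 1.64) and ENSMFAG00000060502 at 0.329 ± 0.289 against 72.1 ± 20.8 CPM (−7.71 ± 0.52). ENSMFAG00000002836 changed by 11.30 ± 1.31 and ENSMFAG00000061395 by −9.60 ± 0.67.

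Sites of the same dog organ gave few calls. Between head and tail of the pancreas (5 libraries each), edgeR called 0 of 14847 genes, with 154 at an unadjusted p under 0.05 and 0 by DESeq2, and 1 gene was called without head replicate 1. The median correlation of a head with a tail library was 0.942 over 25 pairs (range 0.917 to 0.969), beside 0.928 within heads and 0.951 within tails. Between inguinal and mid-back skin (5 each), edgeR called 0 of 17902 genes with 2507 at an unadjusted p under 0.05, and DESeq2 called 701. Mid-back replicates 1 and 5 stood apart, with their nearest libraries in tibial artery and oviduct, and without them edgeR called 3 genes. Between sciatic and tibial nerve (5 each), edgeR called 0 of 17475 genes with 1303 at an unadjusted p under 0.05, and DESeq2 called 11. Sciatic replicate 1 stood apart (median r of 0.763 to its group, against 0.9627), with its nearest library in parathyroid, and without it edgeR again called 0.

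Dog parathyroid (6 libraries) and thyroid (5 libraries) differed in 79 of 18148 genes by edgeR, 20 higher and 59 lower in parathyroid, around a median of 0.114. DESeq2 called 1350. ENSCAFG00845018088 stood at 23 ± 18.2 CPM in parathyroid against 0.204 ± 0.0839 CPM in thyroid (SD; 6.79 ± 1.02, SE, adjusted p = 0.0342), and ENSCAFG00845004472 changed by 6.53 ± 1.22 (adjusted p = 0.0491). ENSCAFG00845006311 stood at 6.11 ± 4.14 against 60.3 ± 25.6 CPM (−3.30 ± 0.54, adjusted p = 0.0342). These calls were lost in 8, 8 and 7 of the 11 fits that left out 1 library, at up to 0.127, 0.171 and 0.127. ENSCAFG00845023629 stood at 0 CPM in every parathyroid library and 32.7 ± 9.72 CPM in thyroid (adjusted p = 0.00458), so no fold change is given. Its call was lost in 4 of the 11 fits, those without any 1 of thyroid replicates 1 to 4, at up to 0.0552. The count itself ran from 0, without any 1 of thyroid replicates 1 to 4, through 1 without parathyroid replicate 2, 3 or 4, 20 without parathyroid replicate 5, 233 without thyroid replicate 5 and 298 without parathyroid replicate 1, to 517 without parathyroid replicate 6. Parathyroid replicate 1 (median r of 0.7808 to its group, against 0.8126) lay nearest to a sciatic nerve library (r = 0.9372), a group in which replicate 1 stood further apart and lay nearest to a parathyroid library at the same r. Thyroid replicate 5 lay nearest to a parathyroid library (r = 0.965). Without both parathyroid replicate 1 and thyroid replicate 5, 501 genes were called.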

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

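The tests of copies that make most of the summed counts, of the direction of shared genes and of immune cell markers were chosen only after the result was seen.

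Single libraries lay far from the rest of their group in 17 of 129 sets of values (13.2%), of which 29 were library totals and 100 levels of single genes in groups of 4 to 10 libraries. Chance gives about 5% of single sets, but several of the 17 come from the same group or library, so that share does not apply directly. The gap to the nearest library is given as a share of the range of the group. Among library totals these were CD1 aorta replicate 3 at 35.65 M counts with the next at 41.16 M (0.538) and dog sciatic nerve replicate 3 at 28.77 M with the next at 38.11 M (0.82). In CD1 atrium, Cacna1h stood at 38.1 CPM in replicate 1 with the next at 14.4 CPM (0.658), and Cd8a at 131 CPM in replicate 8 with the next at 1.12 CPM (0.993). In CD1 atrium replicate 9 the ventricular genes Irx4 at 2.17 CPM (next 0.475, 0.782), Myl2 at 297 CPM (next 144, 0.516) and Myl3 at 415 CPM (next 166, 0.649) were all highest. Rab6b stood at 37.8 CPM in CD1 pituitary replicate 3 (next 7.08, 0.907), Cfap54 at 3.69 CPM in C57BL6 adrenal gland replicate 4 (next 1.7, 0.747) and Myl7 at 13.6 CPM in CD1 left ventricle replicate 2 (next 3.25, 0.864). Cyp2d22 was lowest in CD1 liver replicate 3 at 343 CPM (next 479, 0.855). In C57BL6 striatum replicate 4 the cortical genes Adcyap1 at 5.06 CPM (next 2.37, 0.557), Slc30a3 at 70.7 CPM (next 24.9, 0.654) and Bdnf at 11.3 CPM (next 4.05, 0.657) were highest. In dog right ventricle ENSCAFG00845028634 was lowest in replicate 4 at 4570 CPM (next 7100, 0.882). In monkey motor cortex ENSMFAG00000063427 was lowest in replicate 5 at 20.6 CPM (next 48.4, 0.759), and in monkey hippocampus ENSMFAG00000039947 was highest in replicate 3 at 0.279 CPM (next 0.0564, 0.798).

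The effect of strain differed between tissues in 8778 genes by the interaction test, and 1008 of these passed in opposite directions in different tissues. Among genes named in the report, the log2 fold change, C57BL6 over CD1, of H2-Q2 ran from −7.10 in liver to 0.77 in hypothalamus (interaction adjusted p = 1.44e-29). Cacna1h (5.25e-28), Sfrp5 (3.44e-14) and Lmntd1 (6.48e-12) were highest in atrium at 4.56, 3.09 and 4.35, and lowest in thyroid (−1.51), cortex (−0.61) and pituitary (−1.29). Eps8l1 ran from −1.12 in thyroid to 4.91 in muscle (6.17e-25), Card10 from −1.48 in hypothalamus to 0.39 in atrium (1.57e-24) and Ugt1a6a from −1.73 in muscle to 2.36 in hypothalamus (1.15e-19). Nrn1 ran from −3.99 in pituitary to 0.58 in aorta (5.75e-19), Pcdh20 from −1.27 in aorta to 2.99 in pituitary (2.97e-13) and Kctd4 from −2.67 in thyroid to 2.41 in pituitary (1.32e-12). Slc2a6 ran from −0.66 in aorta to 3.25 in thyroid (1.04e-17) and Adrb3 from −1.58 in liver to 1.76 in thyroid (0.00054). The cholesterol synthesis genes Nsdhl (5.2e-09), Lss (9.06e-08) and Insig1 (1.08e-05) were highest in aorta at 1.34, 1.17 and 1.24, and lowest in muscle (−0.36), liver (−0.72) and pituitary (−0.46). Ppargc1a ran from −0.61 in pituitary to 1.05 in aorta (1.39e-07), Cipc from −0.35 in thyroid to 0.23 in aorta (1.24e-07), Hspa1a from −1.34 in liver to 2.03 in muscle (2.82e-07) and Gabra2 from −0.77 in pituitary to 1.48 in thyroid (3.54e-07). The last were Myh7 from −4.69 in atrium to 1.32 in cortex (5.69e-05), Fosb from −1.82 in adrenal gland to 0.74 in cortex (0.000497), Gbp2 from −0.56 in aorta to 0.65 in pituitary (0.000601), Nr4a1 from −1.51 in atrium to 0.96 in cortex (0.0115) and Myhas from −0.91 in cortex to 3.05 in muscle (0.025).

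In 2 libraries labelled hippocampus the neuron markers were nearly absent, at 0.498% (C57BL6 replicate 1) and 0.613% (CD1 replicate 3) of the other hippocampus libraries, which argues against RNA of another tissue mixed into hippocampal RNA. A wrong label may account for both. The first held Myh6 and Nppa at 31000 and 17400 CPM and correlated with a C57BL6 atrium library at 0.9978, with a chi-square per gene of 2.416 where the next closest pair of libraries had 8.833. The second held Apoa1, Fabp2 and Alpi and lay nearest to a CD1 jejunum library (0.9627), while the 2 libraries labelled CD1 duodenum, in data outside the comparisons, held neuron markers at 93.5% and 78.5% where jejunum held 1.25%. A wrong label may account for these too, and whether they and the CD1 hippocampus library were exchanged cannot be read from the labels.

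Shared strain genes with copies may owe their differences to reads assigned to 1 copy in C57BL6 and to another in CD1. Adding the closest copy left 3% of the median absolute log2 fold change over 68 pairs, but in 39 of these the copy made most of the sum, which by itself dilutes a change. In the other 29 pairs, 31.6% was left (1.79 to 0.56), and 22 copies moved in the opposite direction. The 20% of shared genes without copies stay open, as does a true sequence difference between the strains. Loss of CD1 reads against a reference of another strain is argued against as the cause for all shared genes without copies, since 50% of these (9 of 18) were higher in CD1, which lost reads cannot raise. It stays open for genes with copies and for those higher in C57BL6, 60% of which had a called interaction. That 67.7% of all shared genes were higher in CD1 does not decide it, since a mismatch could also move reads to a copy and raise it.

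The median log2 fold change of interferon-stimulated genes was above 0 in all 9 tissues, with 7 to 21 members called higher, but no list test passed with an estimated correlation (adjusted p = 0.0593 to adjusted p = 0.971). More immune cells in C57BL6 tissue stay open. The medians of macrophage, T cell and B cell markers were all under 50% of the interferon median in 5 tissues. T and B cell medians were 1.80 and 3.17 in thyroid (interferon 0.74), 0.41 and 0.49 in muscle (0.43) and 0.45 and 0.77 in adrenal gland (0.83), and the T cell median was 0.34 in pituitary (0.60). Without the thyroid libraries that stood apart, the medians there were 1.45 and 0.48 (0.53), with 0 of 11 T cell and 1 of 9 B cell markers called, while 14 of 26 interferon genes were. Loss of CD1 reads stays open, as 46.2% of the interferon genes had a called interaction where such loss predicts few. The maps cannot be told apart from the strains, since 0 CD1 libraries belong to the C57BL6 map, so housing, health status or handling may differ along with genotype. A biological strain difference was not tested apart from these and stays open.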

How the results depend on the processing

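Fits without the libraries that stand apart, and fits limited to genes without copies, were chosen only after the data were seen. Over 20 comparisons and 222 alternative fits, the count of called genes stayed within 1.5 times in 185 and moved further in 37, and where no cause is given it was not tested.

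With the DESeq2 Wald test the counts were 1779 in adrenal gland, 2388 in liver, 1386 in muscle, 701 in dog skin (420 higher, 281 lower), 11 in dog nerve and 1350 in dog parathyroid against thyroid. Limited to genes without copies, with fewer genes tested, they were 1686 in cortex, 2043 in hypothalamus, 1850 in aorta, 1749 in thyroid, 548 in adrenal gland, 867 in liver, 475 in muscle and 17 for shared genes. Without the libraries that stand apart they were 3758 in monkey right atrium against ventricle, 3 in dog skin and 501 in parathyroid against thyroid. Adding first-map libraries to the monkey chambers gave 3970. The muscle count fell to 568 without the library whose tissue label is spelled differently. Parathyroid against thyroid gave 49 genes without the filter, 205 with the filter of 1 CPM and 46 without the 1% of genes with the highest counts.

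Leaving out 1 library at a time gave 903 to 1540 genes in liver, 568 to 781 in muscle, 0 to 1 in dog pancreas and 0 to 517 in parathyroid against thyroid. The tissue-enriched genes numbered 9761 at a 2-fold margin. List tests called with an estimated correlation numbered 3 (69 with the preset one).

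Over all alternatives the genes chosen by the naming rule, most of which are named in the text, gave 2599 values, of which 2549 kept direction and call, 49 lost the call and 1 reversed. The reversed value was Cd8a in the atrium strain comparison, at 0.43 with DESeq2 (adjusted p = 0.347); 1 CD1 library held 131 CPM where the next held 1.12 CPM, and the cause was not tested further. Of 96 list tests without the libraries that stand apart, 89 were the same. The 5 that lost their call were circadian clock genes (0.131), keratinocyte (0.121), macrophage (0.223) and T cell markers (0.131) in thyroid and pituitary hormone markers in hypothalamus against hippocampus (0.373). The 2 that gained one were astrocyte markers in thyroid (0.0138, with 4 of 11 lower) and conjugation and transporter genes in aorta (0.0461). At 2-fold the simulated recovery was 45.5% in dog pancreas (5 libraries each) and 82.8% in the cortex strain comparison (12 and 11), and what depth alone limits was not tested. The comparison of chambers across species was not run, since dog and monkey identifiers are paired with no names. No paired analysis was possible because the labels give neither animals nor replicate numbers.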

Other observations

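The comparison of Xist between the sides of a split was chosen only after the split was seen. In dog and monkey the testis held the most tissue-enriched genes, 811 in dog testis tubules and 1290 in monkey testis. Dog whole blood followed with 128 and dog gastrocnemius muscle with 70, and monkey liver with 247 and monkey retina with 119. Of 35 dog tissues 20 held no enriched gene, and of 37 monkey tissues 15. These counts depend on the tissues of a map. The mouse maps hold no testis group and the dog map no liver group, so the leading tissues cannot be compared between species. Sites of the same organ, such as the head, body and tail of dog pancreas, count as separate tissues. A gene equally high in all such sites cannot be enriched in any.

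Other splits of the same libraries into groups of the same sizes gave fewer called genes than the real one in most comparisons. This argues against a random division of the libraries as the source of the counts there. The splits treat libraries as exchangeable, although the labels do not say which of them share an animal. In the strain comparisons the real count and the highest of the other splits, over 100 splits each, were 2596 and 1 in cortex, 3198 and 2488 in hypothalamus, 3257 and 1278 in atrium, 2845 and 297 in aorta, 4095 and 1618 in pituitary, 2633 and 83 in thyroid, 1465 and 576 in liver and 859 and 127 in muscle. In adrenal gland 2 of 100 splits, the real one included, reached the real count of 1100, and the other called 2557 genes. That split put C57BL6 replicates 3, 4 and 5 with CD1 replicates 3, 6 and 7, so the adrenal libraries hold a structure across the strains that the labels do not name. The level of Xist parted these sides, at 0.0966 to 0.368 CPM in 6 libraries and 1.91 to 471 CPM in the other 7. The labels give no sex, so the sex of the animals was not in the model and stays open. In the other strain comparisons the Xist ranges of the corresponding sides overlapped. For genes shared by all 9 tissues the values were 93 and 0, and for the interaction of strain and tissue 8778 and 2741, over 24 splits each that redrew the strain labels within each tissue. Labels were redrawn separately in each tissue, which by itself makes a gene shared by all 9 unlikely. The 0 therefore does not test whether the 93 arose by chance. The median of the other interaction splits was 1218 genes, so part of the 8778 is what this test calls under redrawn labels. The splits with high counts in hypothalamus, atrium and pituitary held mostly C57BL6 libraries on 1 side, so they partly follow the strains.

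Between tissues, the real count and the highest other were 7568 and 9 for mouse atrium against left ventricle, 6131 and 19 for the dog chambers, 2095 and 1432 for the monkey chambers, 6435 and 2769 for monkey striatum against motor cortex and 4954 and 1778 for monkey hypothalamus against hippocampus, over 100 splits each. Over 50 splits they were 10560 and 0 for mouse striatum against cortex and 10533 and 1453 for mouse hypothalamus against hippocampus. In dog parathyroid against thyroid 2 of 100 splits, the real one included, reached the real count of 79, and the other, which put parathyroid replicate 6 with all 5 thyroid libraries, called 647 genes. In the dog pancreas, skin and nerve comparisons edgeR called 0 genes, a count that any split reaches (100 of 100), so the splits say nothing about chance there. The highest other splits called 5, 90 and 2 genes. The skin split with 90 genes put mid-back replicates 1 and 5, which stood apart, with inguinal replicates 1, 2 and 5.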
